A study of Homo sapiens with 24 samples.

How the data were processed

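The series holds QuantSeq 3′ FWD mRNA libraries of 786-M1A-Cl6, a human clear cell renal carcinoma line grown in RPMI with serum, in 6 groups of 4 replicates. Each deposited file gives the read counts of 1 library per Ensembl gene, made with STAR 2.5.2a and HTSeq 0.6.0 on hg38, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. The files held 60107 gene identifiers, of which 56104 had a symbol in GENCODE release 44, and identifiers without a symbol took at most 0.188% of counts. In 20 files 97 rows had no identifier, and 3 to 4 of these rows were above 0 and held 53.7% to 66.0% of the counts in the file. The 4 control files had no such rows. Rows without an identifier were left out of all 24 libraries, after which totals ran from 7840439 to 11492907 counts. Within each group every pair of replicates differed by more than counting error, so no library was a copy of another of its group.

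The groups were control cells (shCtrl_sgCtrl, A), PAX8 hairpin cells (shPAX8_sgCtrl, A), and PAX8 hairpin cells with SMARCB1 guide 1 or guide 2, each as A and as LT. The labels name 1 PAX8 hairpin and do not spell out A and LT. The comparisons were PAX8 hairpin against control cells, each guide against PAX8 hairpin cells in A, LT against A within each guide, guide 2 against guide 1 in A, and the difference between the guides in LT minus A. Intersections gave the genes shared by both guides and the genes called for the hairpin that passed in the opposite direction with both guides. These comparisons, their tests, the gene lists and most alternatives were set before the data were examined.

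Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total count 15), and a robust quasi-likelihood F test in 1 fit of all 24 libraries with 18 residual degrees of freedom. Of all genes 13867 passed the filter. Benjamini-Hochberg adjustment was made within each comparison, and a gene was called at an adjusted p below 0.05. Calls of at least 2-fold were counted as well. PAX8 and SMARCB1 were also compared by a two-sided exact permutation test of log2(CPM + 1). Gene models gave chromosome, start and end. A count of 0 was read as an upper limit of 3 counts, which with the 95% intervals of ratios covers counting error only, since the reads carry no molecular identifiers in the files. In 1 simulated set with known changes in the PAX8 hairpin comparison (13621 genes), the changed genes were drawn from those above 3 CPM on average. Of these, edgeR recovered 74 of 100 genes changed 2-fold and 98 of 100 changed 4-fold. False calls made up 4.97% of its calls, against 13.53% for DESeq2 and 3.95% for limma-voom. The counts were drawn independently with edgeR's own estimates of spread. They hold no libraries that stand apart and no correlated replicates, so error rates in the real data may differ.

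The genes named were PAX8 and SMARCB1 and, for the hairpin, the guides and LT minus A, the 8 genes that rose and the 8 that fell most, ranked for the guides and LT by the smaller of the changes of both guides. They had to pass the test, reach a mean of 10 CPM in the higher group and show no overlap between the replicates compared, and 4 genes per direction were taken in the same way for the differences between guides. XIST, Y-linked genes, pseudogenes and genes without an ordinary symbol were left out of this choice. Not every gene chosen in this way is described. From each list described, up to 4 members with the smallest adjusted p could be named. The 32 gene lists were written from general knowledge. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in 1 direction. Adjustment was over the lists of 1 comparison, and lists with fewer than 3 tested genes had no set test. Camera adjusted p are at the preset correlation unless stated, and can be much larger with an estimated one.

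Several named genes overlap another gene's exons, and where the counting was not stranded, reads of the opposite strand would be included. On the opposite strand these are PAX8 with PAX8-AS1, SMARCB1 with DERL3, DCDC2 with KAAG1, MAL2 with MAL2-AS1, LRATD2 with PCAT1, TNC with DELEC1, BHLHE41 with SSPN, APCDD1L-DT with APCDD1L and CRYBG1 with RTN4IP1, and ADGRL1, B3GALT5, C15orf48, CDH13, CUL9, F2R, FABP6, GASK1B, PAQR5, SCG5, SEMA6A and ZNF793 with noncoding RNAs. On the same strand NME4 overlaps DECR2 and SCG5 overlaps ARHGAP11A-SCG5, and B3GALT5, C15orf48 and PAQR5 overlap noncoding RNAs. Reads of metallothionein, histone and interferon-induced paralogs can be hard to place.

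The alternatives were DESeq2 size factors or library size alone in place of TMM, no filter on low counts, DESeq2 1.42.0 and limma-voom as tests, a fit of the compared groups only, replicate number as a block, an adjusted p under 0.01, a pseudocount of 0.5 CPM for the target levels, and leaving out each replicate in turn. Leaving out control replicate 2 and guide 1 LT replicate 4 together was added after seeing the data. Centred profiles of replicates with the same number were positively correlated in guide 2 against guide 1 in A (0.26, 0.155, 0.182 and 0.361). The same held in LT minus A with guide 1 (0.079, 0.198, 0.174 and 0.619). In the other comparisons both signs occurred, with 0.524 for replicate 2 in the hairpin comparison. Overlaps of calls were set beside simulations of unchanged groups, independent lists, and all 6 splits of the shared PAX8 hairpin libraries 2 against 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.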

Results

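Gene expression was measured in 786-M1A-Cl6, a human clear cell renal carcinoma line, by QuantSeq 3′ mRNA sequencing, in which each read reports the 3′ end of a transcript. The 24 libraries fell into 6 groups of 4. Control cells carried a control hairpin and a control guide RNA (shCtrl, sgCtrl). PAX8 hairpin cells carried a short hairpin RNA against PAX8 and the control guide. The remaining 4 groups carried the PAX8 hairpin with guide 1 or guide 2 against SMARCB1, and for each guide there was a group with the label A and a group with the label LT. Both groups with the control guide have the label A. The labels do not spell out A or LT, and with no control guide group under LT, LT was compared with A within each guide. The title of the series gives SMARCB1 and lineage fidelity in renal cancer as its subject. Gene counts per library ranged from 7840439 to 11492907, and 17680 to 19204 genes had at least 1 count. A count of 0 allowed up to 0.261 to 0.383 CPM (counts per 1e6 counts of the library), which covers counting error only. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. CPM values below are means ± SD and log2 fold changes are ± SE, with n = 4 per group.

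The targeted genes were examined first. PAX8, a paired-box transcription factor of kidney development (ENSG00000125618, hg38 chromosome 2, 113215997 to 113278921, minus strand), was lowered by the hairpin. It stood at 118 ± 24.3 CPM in control cells and 32.9 ± 2.77 CPM in PAX8 hairpin cells, which is 27.7% of the control mean (log2 fold change -1.85 ± 0.16, edgeR adjusted p = 9.87e-09). SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex (ENSG00000099956, chromosome 22, 23786931 to 23838009, plus strand), stood at 29.1 ± 1.37 CPM in PAX8 hairpin cells, 3.86 ± 1.22 CPM with guide 1 and 4.85 ± 1.10 CPM with guide 2, both A. These levels are 13.3% and 16.7% of the PAX8 hairpin mean, with log2 fold changes of -2.90 ± 0.24 (edgeR adjusted p = 1.08e-09) and -2.58 ± 0.24 (adjusted p = 3.07e-08). The 3′ tags measure transcript level and cannot show the change a guide makes in the DNA. A two-sided exact permutation test of log2(CPM + 1) over the 70 assignments of 4 against 4 libraries gave p = 0.02857, the smallest it allows, for each of these 3 differences.

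Both targeted genes also moved outside their own comparison. PAX8 was higher with the SMARCB1 guides than in PAX8 hairpin cells, at 56.3 ± 7.70 CPM with guide 1 (log2 fold change 0.78 ± 0.16, edgeR adjusted p = 0.000592) and 48.9 ± 4.15 CPM with guide 2 (0.57 ± 0.16, adjusted p = 0.0179). The guide 2 call was lost on leaving out any of 4 libraries, with an adjusted p of 0.0742 (0.00202 to 0.0742 over the alternatives) without PAX8 hairpin replicate 3, 0.0553 without its replicate 4, 0.0656 without guide 2 A replicate 2 and 0.0536 without its replicate 4. From A to LT, PAX8 was 72.7 ± 15.1 CPM with guide 1, a difference that did not pass the test (log2 fold change 0.37 ± 0.16, edgeR adjusted p = 0.161). Over the alternatives that adjusted p ranged from 0.0404, without guide 1 LT replicate 3, to 0.389. With guide 2 PAX8 fell to 28.3 ± 4.24 CPM (-0.79 ± 0.16, adjusted p = 0.00161). The difference between the guides in that change was -1.16 ± 0.22 (edgeR adjusted p = 0.00129). SMARCB1 was 41.5 ± 8.73 CPM in control cells, and its difference to PAX8 hairpin cells did not pass the test across all genes (log2 fold change -0.51 ± 0.21, edgeR adjusted p = 0.101). It passed with limma-voom (adjusted p = 0.0393), with replicate number as a block (0.0449) and in a fit of the compared groups only (0.0390), over a range of 0.0390 to 0.330. The exact permutation test of SMARCB1 alone gave p = 0.02857 there, and p = 0.05714 on leaving out any 1 of the 4 PAX8 hairpin libraries. In LT, SMARCB1 stood at 4.89 ± 1.93 CPM with guide 1 and 8.48 ± 1.72 CPM with guide 2. The guide 2 rise (0.80 ± 0.24, edgeR adjusted p = 0.0358) gave an exact permutation p of 0.05714 and was lost with limma-voom (adjusted p = 0.0508). It was also lost on leaving out any of 6 libraries, replicates 1, 2 and 4 of guide 2 A (adjusted p of 0.104, 0.112 and 0.0699) and replicates 2, 3 and 4 of guide 2 LT (0.0754, 0.0928 and 0.066), against 0.00923 at the lowest.

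**Figure D1:**
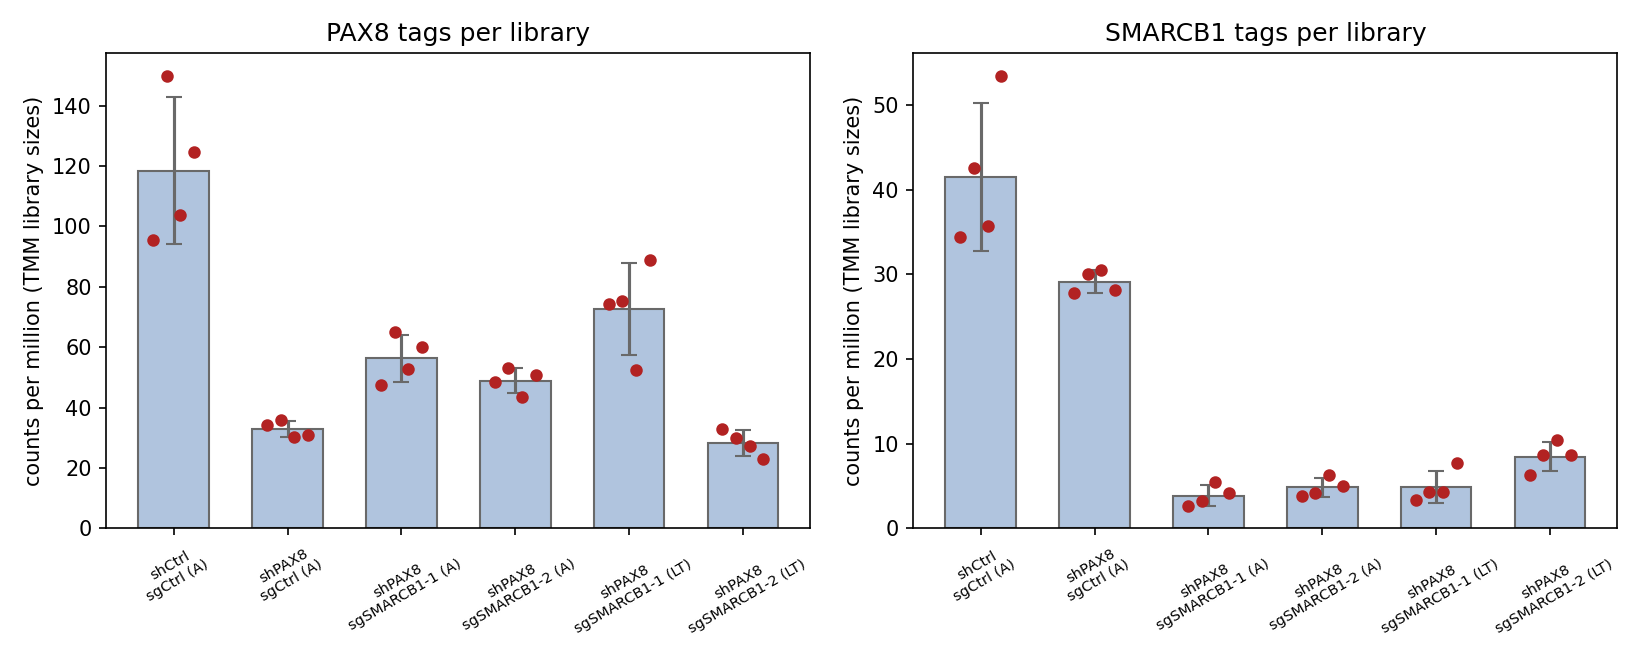
CPM of PAX8 and SMARCB1 in each of the 24 libraries (points), with the mean and SD of each group of 4 (bars and error bars), on linear axes that start at 0. PAX8 falls from 118 CPM in control cells to 32.9 CPM in PAX8 hairpin cells, and SMARCB1 lies between 3.86 and 8.48 CPM on average in the 4 groups with a SMARCB1 guide.

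The PAX8 hairpin comparison asked what changes with the hairpin that lowers PAX8. The labels name 1 PAX8 hairpin, so its effects on other targets cannot be told apart from those of lowered PAX8. PCLO, a scaffold protein of the presynaptic active zone (ENSG00000186472, chromosome 7, 82754012 to 83162930), rose from 2.04 ± 0.45 to 28.5 ± 5.58 CPM (log2 fold change 3.80 ± 0.21). CYTIP rose by 3.45 ± 0.21, WNT5A, a Wnt ligand, by 3.12 ± 0.37, and C5orf46 by 3.00 ± 0.40. The carboxypeptidases CPA4 and CPE rose by 3.09 ± 0.36 and 2.80 ± 0.16. The tyrosine kinase gene FYN rose by 2.69 ± 0.37 and the thrombin receptor gene F2R by 2.67 ± 0.17. CLEC4E, a C-type lectin receptor (ENSG00000166523, chromosome 12, 8533305 to 8540905), went from 14.5 ± 3.26 to 0.55 ± 0.22 CPM (-4.69 ± 0.34). The potassium channel gene KCNK3 changed by -4.13 ± 0.28, LINC02274 by -3.78 ± 0.41 (-4.50 without PAX8 hairpin replicate 1) and the EGF receptor ligand gene EREG by -2.98 ± 0.25. SEMA6A changed by -2.84 ± 0.31, LRRN4 by -2.76 ± 0.21 and DCDC2 by -2.68 ± 0.17. These 15 genes had edgeR adjusted p from 1.26e-11 to 1.04e-05. Of 13867 genes tested, 2338 passed, 1200 higher and 1138 lower, and 723 of them changed at least 2-fold. Scaled by library size alone, 1490 were higher and 847 lower, so the share of higher calls moved from 51.3% to 63.8%.

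Among the gene lists, proliferation genes stood out in the PAX8 hairpin comparison. Of 60 cell cycle genes, 38 fell, 1 rose and 21 did not pass (44 fell and 1 rose when adjusted over the list alone; camera adjusted p = 1.75e-19, and adjusted p = 9.57e-06 with an estimated correlation). HMMR, a mitotic spindle protein, went from 325 ± 51.5 to 137 ± 3.33 CPM and the replicative helicase subunit MCM7 from 427 ± 86.6 to 217 ± 16.8 CPM. GINS1 went from 35.5 ± 5.27 to 19.0 ± 1.36 CPM and the replication licensing factor CDC6 from 49.0 ± 3.44 to 27.0 ± 1.25 CPM. Of 44 MYC targets, 17 fell (21 adjusted over the list alone; adjusted p = 7.25e-07), among them RRP9 (log2 fold change -1.02 ± 0.13) and CAD (-0.47 ± 0.10). Of 25 p53 targets, 7 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000118). The cell cycle inhibitor CDKN1A went from 287 ± 37.3 to 489 ± 11.1 CPM and TP53INP1 from 3.48 ± 0.80 to 18.03 ± 2.21 CPM.

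Epithelial and mesenchymal genes moved in opposite directions with the hairpin. Of 24 epithelial identity genes, 7 fell and 17 did not pass (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000366). Among them were the tight junction gene CLDN1 (-1.51 ± 0.14), EPCAM (-1.75 ± 0.34) and the keratin gene KRT18 (-0.63 ± 0.13). Of 33 mesenchymal genes, 13 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 0.000273). SPARC rose from 404 ± 68.9 to 1097 ± 100 CPM, LOXL2 from 135 ± 22.7 to 311 ± 57.0 CPM, ACTA2 by 0.96 ± 0.16 and COL1A1 by 1.44 ± 0.26 on the log2 scale. As markers of other cells, 3 of 5 fibroblast genes rose, ACTA2 and COL1A1 among them (adjusted p = 0.006, and adjusted p = 0.0297 with an estimated correlation). Of 30 NF-κB and inflammation genes, 11 fell (14 adjusted over the list alone; adjusted p = 8.28e-07), including BIRC3 (-1.22 ± 0.11), SAA1 (-2.28 ± 0.34) and CXCL1 (-1.98 ± 0.31). Of 45 interferon response genes, 14 fell and 4 rose (15 and 6 adjusted over the list alone; adjusted p = 0.0282). That call gave adjusted p = 0.0962 with an estimated correlation and was lost in a fit of the compared groups only. Of 18 nephron lineage transcription factors, 5 rose and 3 fell, without a direction as a list (adjusted p = 0.887), and besides PAX8 itself LHX1 fell (-1.08 ± 0.21) while TFAP2A (1.54 ± 0.18) and MAF (1.27 ± 0.24) rose. The 4 control files were the only ones without rows lacking an identifier, so the form of the files differs along this comparison. On the second principal component control replicate 2 lay at -57.8, and without it and guide 1 LT replicate 4, an omission chosen after seeing the data, 2739 genes passed.

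The guide comparisons asked what SMARCB1 loss changes in cells with the PAX8 hairpin. KISS1R, the kisspeptin receptor (ENSG00000116014, chromosome 19, 917287 to 921005), went from 2 counts in the 4 PAX8 hairpin libraries together to 40.1 ± 4.38 CPM with guide 1 and 10.3 ± 0.90 CPM with guide 2. The ratios to PAX8 hairpin cells were 693 (95% counting interval 192 to 5730) and 178 (48.8 to 1470). EREG rose from 6.57 ± 0.81 to 232 ± 53.01 and 75.9 ± 9.88 CPM. MAP2, a microtubule-associated protein of neurons, rose from 6.11 ± 1.53 to 54.5 ± 10.1 and 97.4 ± 12.8 CPM, and the arrestin gene ARRB2 from 8.52 ± 1.45 to 90.4 ± 7.09 and 57.0 ± 9.45 CPM. C11orf86, DCDC2, C15orf48 and RAB42 rose by 5.68 ± 0.41, 3.99 ± 0.17, 4.56 ± 0.56 and 3.28 ± 0.32 on the log2 scale with guide 1. With guide 2 they rose by 5.32 ± 0.41, 3.45 ± 0.17, 3.28 ± 0.53 and 2.64 ± 0.32. IL7R, a cytokine receptor gene (ENSG00000168685, chromosome 5, 35852695 to 35879603), fell from 377 ± 6.10 to 9.05 ± 1.00 CPM with guide 1 and 40.7 ± 3.53 CPM with guide 2. The neuroendocrine gene SCG5 fell from 81.4 ± 6.96 to 7.54 ± 1.75 and 12.3 ± 1.00 CPM. Tissue factor (F3) fell from 20.6 ± 3.73 to 2.37 ± 0.77 and 2.89 ± 0.49 CPM, and the matrix protein gene TNC from 12.8 ± 2.76 to 0.54 ± 0.32 and 1.91 ± 0.15 CPM. HNMT, LINC01929, FYN and FOLR1 changed by -3.80 ± 0.35, -5.14 ± 0.33, -3.09 ± 0.38 and -5.82 ± 0.49 with guide 1. Their changes with guide 2 were -2.92 ± 0.33, -2.86 ± 0.27, -2.67 ± 0.36 and -2.65 ± 0.36. The largest edgeR adjusted p among these 16 genes was 2.33e-06 with guide 1 and 0.000229 with guide 2.

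With guide 1, 3056 genes passed, 1588 higher and 1468 lower, 1314 of them by at least 2-fold. With guide 2 these counts were 1457, 725, 732 and 572, and a fit of the compared groups only called 2210. In the same direction with both guides, 1211 genes passed, 608 higher and 603 lower, and 7 passed in opposite directions. Both comparisons used the same 4 PAX8 hairpin libraries. A simulation without an effect in any group shared 0 calls under edgeR, which decides little, since it leaves almost nothing to call. Independent lists of these sizes would share 160.5, and with the PAX8 hairpin libraries split 2 against 2 between the guides 614 to 667 genes were shared. Across genes, which are not independent replicates, the log2 fold changes of the guides had a Pearson r of 0.806 (0.508 to 0.642 over the splits and 0.5 in the simulation) and a covariance of 0.382 against 0.0442 simulated.

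**Figure D2:**
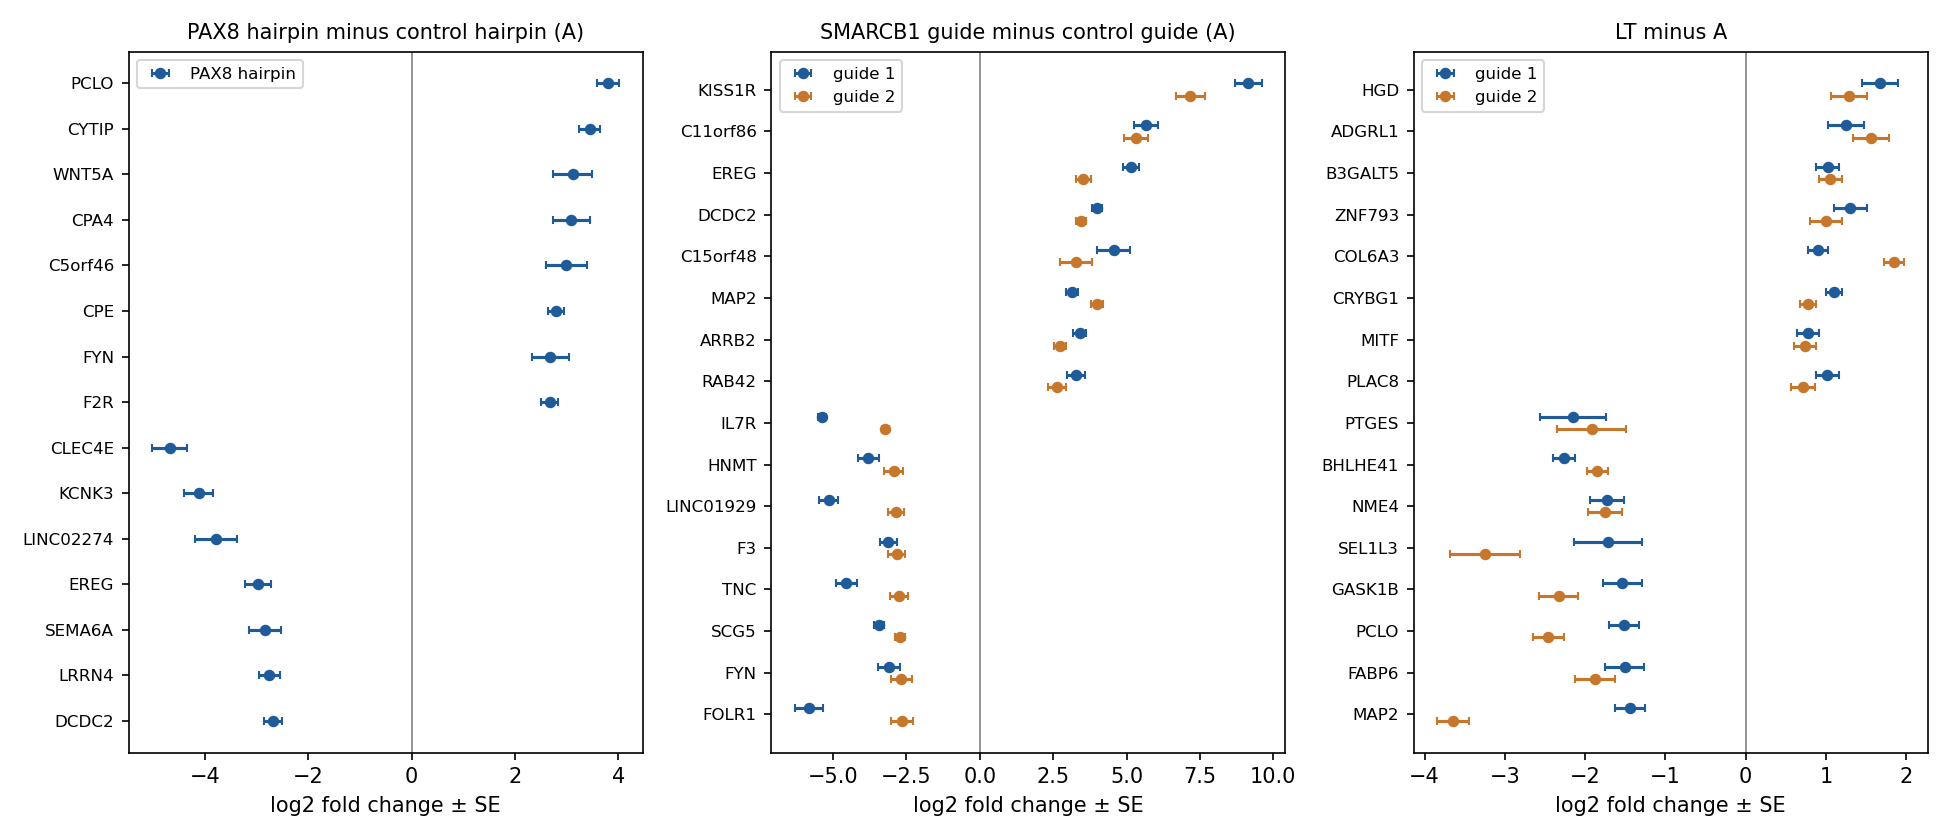
Log2 fold changes (x axis) with SE bars of the 15 named genes of the PAX8 hairpin comparison and the 16 each of the SMARCB1 guide comparisons and of the LT minus A comparisons, with the 2 guides drawn as separate points. KISS1R lies farthest to the right, at 9.14 with guide 1 and 7.17 with guide 2.

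Hypoxia-inducible factor (HIF) targets rose on balance with both guides. Of 35 tested, 24 rose and 5 fell with guide 1 (24 and 5 adjusted over the list alone; camera adjusted p = 7.66e-25, and adjusted p = 0.000154 with an estimated correlation). With guide 2, 13 rose and 3 fell (17 and 5; adjusted p = 1.6e-06, and adjusted p = 0.0297 with an estimated correlation), and 13 rose with both. EPAS1, which encodes HIF-2α, rose from 43.6 ± 1.46 to 278 ± 15.4 and 137 ± 6.45 CPM. DDIT4, an inhibitor of mTOR signalling, rose from 47.6 ± 6.81 to 225 ± 30.03 and 137 ± 21.03 CPM, while STC2 fell from 485 ± 16.7 to 161 ± 29.9 and 143 ± 9.86 CPM. Of 24 epithelial identity genes, 8 rose with guide 1 (9 adjusted over the list alone; adjusted p = 1.27e-06), and 7 rose and 2 fell with guide 2 (9 and 2; adjusted p = 1.68e-06). CLDN1 went from 17.6 ± 1.32 to 148 ± 22.0 and 71.0 ± 7.67 CPM and the keratin gene KRT19 from 128 ± 7.52 to 419 ± 46.6 and 310 ± 13.5 CPM. The epithelial transcription factor gene ELF3 went from 5.29 ± 0.61 to 25.9 ± 1.87 and 23.5 ± 2.54 CPM.

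Mesenchymal genes fell with both guides. Of 33 tested, 17 fell and 2 rose with guide 1 (17 and 2 adjusted over the list alone; camera adjusted p = 3.14e-14) and 17 fell with guide 2 (19 fell and 1 rose; adjusted p = 1.05e-11), 14 of them with both. Fibronectin (FN1) went from 116 ± 7.32 to 8.34 ± 2.87 and 37.5 ± 4.04 CPM. The activin subunit gene INHBA went from 307 ± 20.95 to 71.8 ± 6.10 and 108 ± 12.9 CPM, and the receptor tyrosine kinase gene AXL from 188 ± 15.7 to 102 ± 4.5 and 107 ± 9.65 CPM. Of 29 collagen, laminin and other matrix genes, 12 fell and 4 rose with guide 1 (12 and 4 adjusted over the list alone; adjusted p = 0.00059) and 12 fell and 2 rose with guide 2 (13 and 2; adjusted p = 1.6e-06). COL8A1 changed by -0.67 ± 0.10 and -1.09 ± 0.10 and COL13A1 by -2.14 ± 0.26 and -1.73 ± 0.26 on the log2 scale. The lists overlap, since FN1 and TNC stand among the mesenchymal genes and FN1 also among the matrix genes. As markers of other cells, 3 of 5 fibroblast genes fell with each guide (camera adjusted p = 0.0172 and 0.0260), with adjusted p = 0.065 and 0.0629 with an estimated correlation. Of those 5 genes 4 are also on the mesenchymal or matrix lists.

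Immune signalling and proliferation genes rose on balance. Of 45 interferon response genes, 20 rose and 7 fell with guide 1 (22 and 8 adjusted over the list alone; camera adjusted p = 0.00844, and adjusted p = 0.065 with an estimated correlation). With guide 2, 15 rose and 3 fell (21 and 7; adjusted p = 1.6e-06). IFIT1 went from 9.94 ± 0.60 to 23.97 ± 1.84 and 30.6 ± 3.23 CPM. The RNA sensor gene IFIH1 went from 8.87 ± 1.20 to 33.0 ± 11.6 and 24.4 ± 3.70 CPM, and HERC5 from 3.48 ± 0.56 to 12.6 ± 0.57 and 10.9 ± 4.05 CPM. Of 30 NF-κB and inflammation genes, 17 rose and 4 fell with guide 1 (20 and 4 adjusted over the list alone; adjusted p = 1.27e-06) and 7 rose and 2 fell with guide 2 (12 and 3; adjusted p = 6.32e-05). BIRC3, an inhibitor of apoptosis, rose from 64.9 ± 7.05 to 301 ± 8.75 and 199 ± 13.1 CPM. The chemokine gene CXCL5 rose from 10.1 ± 1.12 to 87.2 ± 22.1 and 30.5 ± 0.40 CPM, while PTX3 fell from 14.8 ± 0.69 to 2.65 ± 0.08 and 5.21 ± 0.85 CPM. Of 60 cell cycle genes, 11 rose and 1 fell with guide 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00844, and adjusted p = 0.065 with an estimated correlation). With guide 2, 13 rose (19; adjusted p = 4.1e-07). E2F2 rose from 9.34 ± 0.88 to 35.9 ± 4.11 and 22.5 ± 3.09 CPM.

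Nephron lineage transcription factors went both ways with the guides. Of 18 tested, 7 rose and 3 fell with guide 1 (8 and 3 adjusted over the list alone; camera adjusted p = 0.470) and 3 rose and 4 fell with guide 2 (4 and 4; adjusted p = 0.398). IRX3 rose from 84.7 ± 4.66 to 161 ± 13.8 and 129 ± 7.34 CPM. MAF fell from 48.2 ± 8.22 to 16.7 ± 3.23 and 25.3 ± 3.32 CPM and TFCP2L1 from 7.73 ± 2.03 to 0.22 ± 0.13 and 1.45 ± 0.43 CPM. Mitochondrially encoded genes took 10.1 ± 0.40% of counts in PAX8 hairpin cells, 12.02 ± 1.05% with guide 1 and 11.3 ± 0.55% with guide 2. Of the 13 mitochondrially encoded genes, 5 rose with guide 1 (camera adjusted p = 0.0107, and adjusted p = 0.33 with an estimated correlation), and the list did not pass with guide 2 (adjusted p = 0.267).

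**Figure D3:**
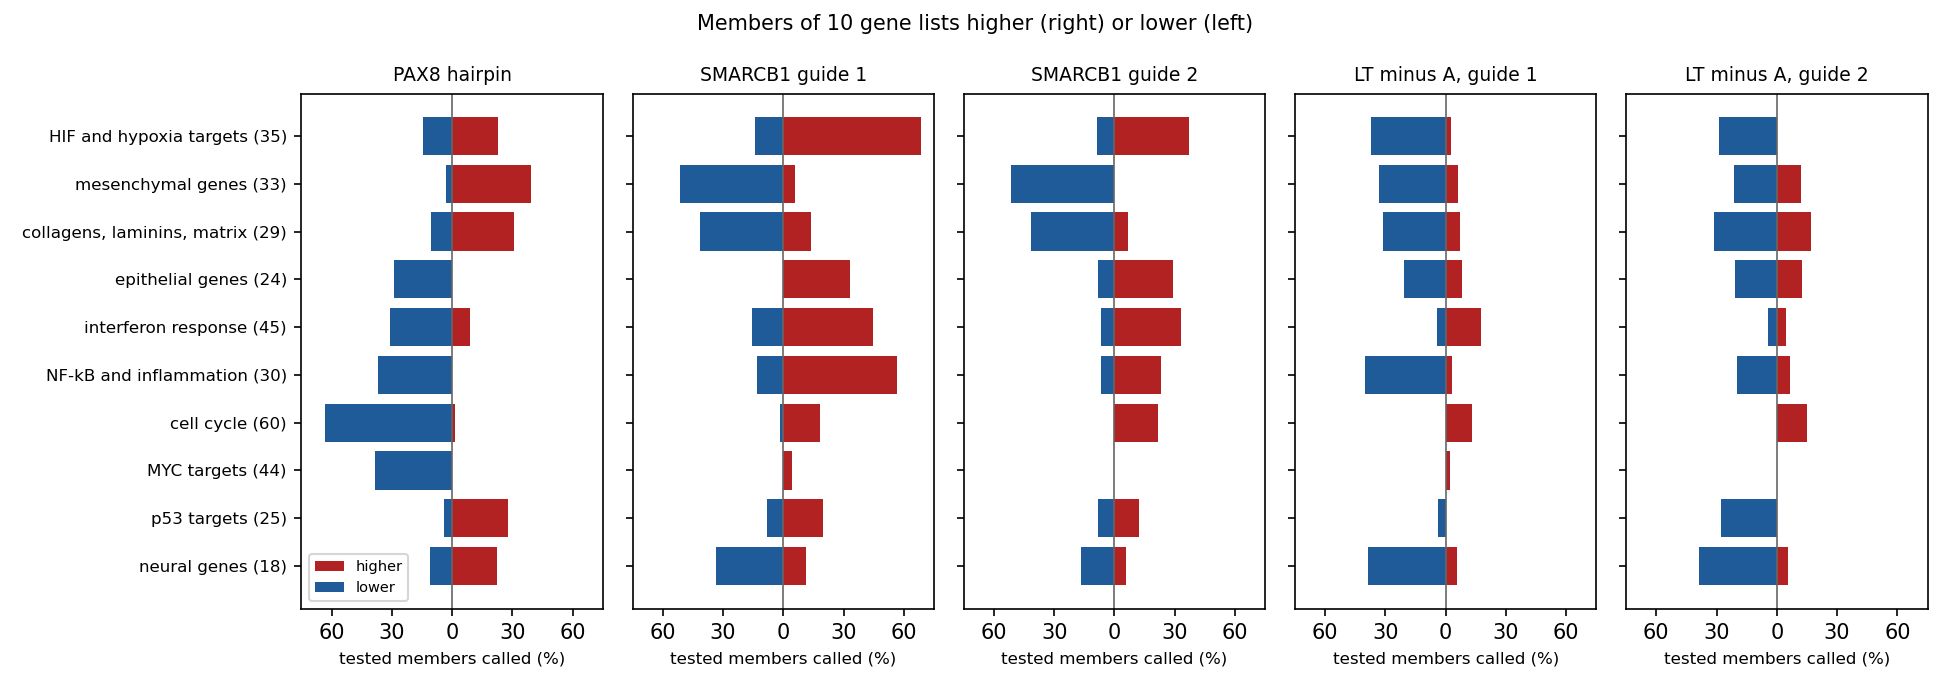
Percent of the tested members of 10 gene lists (x axis; number tested in parentheses) called higher (red bars, right) or lower (blue bars, left) by edgeR in 5 comparisons. Of the 35 HIF targets, 24 were higher with guide 1 and 13 with guide 2, and of the 60 cell cycle genes 38 were lower with the PAX8 hairpin.

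Genes changed by the PAX8 hairpin were then followed into the guide comparisons. Of the 15 named genes of the hairpin, 11 passed in the opposite direction with both guides, all except PCLO, CLEC4E, KCNK3 and LRRN4. Every group with a SMARCB1 guide also carried the PAX8 hairpin. Reversal here thus means opposite directions, and a guide effect that does not need the hairpin cannot be told apart. EREG stood at 51.8 ± 12.4 CPM in control cells, 6.57 ± 0.81 CPM with the hairpin and 232 ± 53.01 CPM with the hairpin and guide 1. FYN stood at 1.85 ± 0.69, 11.99 ± 2.5 and 1.38 ± 0.66 CPM in the same 3 groups. By list, 11 interferon response genes, 4 cell cycle genes, 3 NF-κB and inflammation genes, 2 HIF targets and 2 epithelial genes fell with the hairpin and rose with both guides. In the other direction 8 mesenchymal genes, 2 interferon response genes and 1 HIF target rose with the hairpin and fell with both.

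Of the 2338 genes called for the hairpin, 440 (18.8%) passed in the opposite direction with both guides, 238 that had risen and 202 that had fallen, and 83 passed in the same direction with both. The PAX8 hairpin libraries entered these comparisons with opposite signs, which by itself gives a negative correlation. Independent calls would reverse 102.1 genes. In 20 simulations without an effect in any group 0 genes reversed under edgeR, which decides little, since such data leave almost nothing to call. With those libraries split 2 against 2 between the comparisons, 198 to 228 of 1223 to 1524 called genes reversed (13.7% to 16.5%) and 29 to 44 kept their direction. Across genes, the correlation of the hairpin effect with guide 1 was -0.325 (-0.504 simulated, and -0.244 to -0.159 over the splits) and with guide 2 -0.329 (-0.5 simulated, and -0.202 to -0.097 over the splits). The covariances were -0.168 and -0.113, against -0.0443 and -0.0444 simulated.

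**Figure D4:**
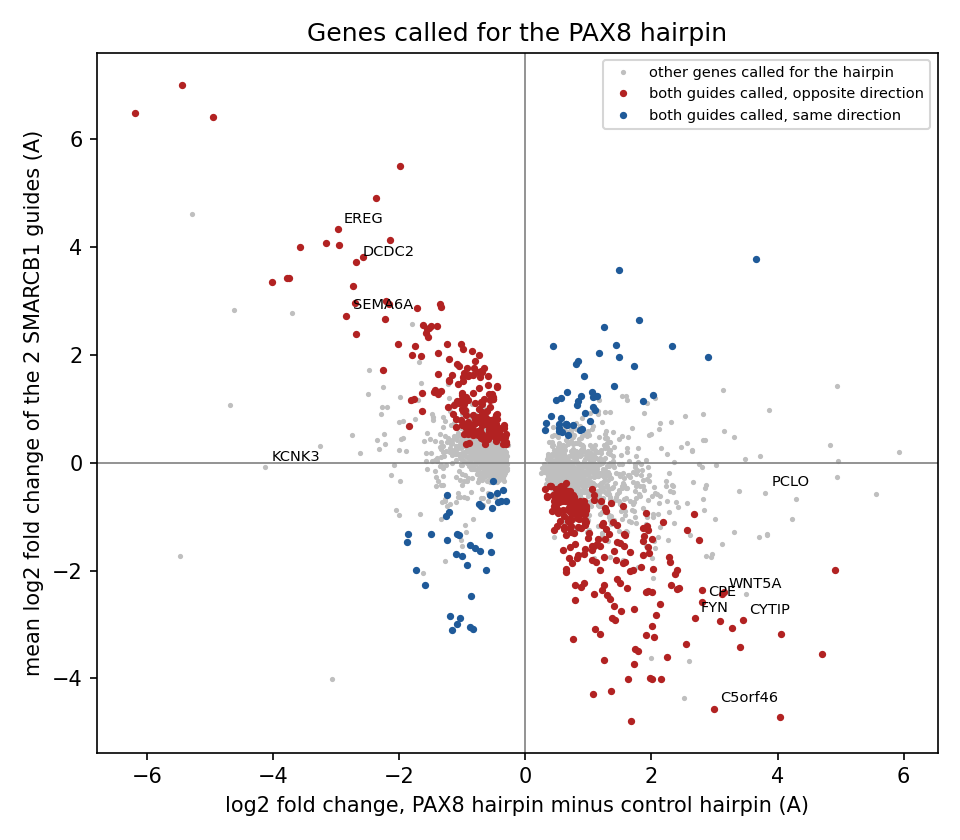
Mean log2 fold change of the 2 SMARCB1 guides (y axis) against the log2 fold change of the PAX8 hairpin (x axis) for the genes called for the hairpin. The 440 reversed by both guides are red, the 83 that kept their direction with both are blue and the others are grey. The reversed genes fill the upper left and lower right, and part of the negative slope comes from the PAX8 hairpin libraries that both axes share.

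Under the label LT, the cells of both guides differed from those under A. The transcription factor gene BHLHE41 fell from 32.8 ± 5.34 to 6.83 ± 0.60 CPM with guide 1 and from 32.9 ± 4.58 to 9.13 ± 0.47 CPM with guide 2. MAP2 fell from 54.5 ± 10.1 to 20.1 ± 3.50 and from 97.4 ± 12.8 to 7.79 ± 1.48 CPM, and PCLO from 17.0 ± 2.17 to 5.93 ± 1.44 and from 22.2 ± 1.57 to 4.02 ± 0.76 CPM. The prostaglandin E synthase gene PTGES, NME4, GASK1B and FABP6 changed by -2.15 ± 0.41, -1.73 ± 0.21, -1.54 ± 0.24 and -1.51 ± 0.24 on the log2 scale with guide 1. With guide 2 they changed by -1.92 ± 0.43, -1.75 ± 0.21, -2.33 ± 0.24 and -1.88 ± 0.25. Without guide 1 LT replicate 4 the guide 1 value of PTGES was -2.98. SEL1L3 changed by -1.71 ± 0.42 and -3.25 ± 0.44, and its guide 1 call was lost in a fit of the compared groups only and with limma-voom. In the other direction HGD, an enzyme of tyrosine breakdown, went from 8.02 ± 1.03 to 25.6 ± 2.97 and from 6.52 ± 1.04 to 15.9 ± 5.52 CPM. The collagen gene COL6A3 went from 98.4 ± 11.9 to 183 ± 27.1 and from 70.8 ± 6.04 to 254 ± 29.8 CPM, and MITF, a transcription factor gene, from 32.1 ± 3.67 to 54.8 ± 8.19 and from 28.1 ± 2.27 to 46.9 ± 4.81 CPM. ADGRL1, B3GALT5, ZNF793, CRYBG1 and PLAC8 rose by 1.25 ± 0.23, 1.02 ± 0.14, 1.30 ± 0.20, 1.10 ± 0.10 and 1.02 ± 0.15 with guide 1. With guide 2 the rises were 1.56 ± 0.23, 1.06 ± 0.14, 1.00 ± 0.20, 0.77 ± 0.10 and 0.71 ± 0.15.

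LT minus A called 1188 genes with guide 1, 447 higher and 741 lower, and 1109 with guide 2, 380 higher and 729 lower, by edgeR at an adjusted p below 0.05. At least 2-fold changes made up 445 and 489 of these. In the same direction with both guides, 232 genes passed, 65 higher and 167 lower, against 51.2 for independent lists, and 103 passed in opposite directions against 43.8. No library entered both comparisons, and the log2 fold changes of the guides had a Pearson r of 0.235 across genes. A fit of the compared groups only called 532 genes with guide 1, and 119 were shared. Guide 1 LT replicate 4 lay at -73.2 on the second principal component, and without it and control replicate 2 the genes higher in LT with guide 2 numbered 580.

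HIF targets as a list were lower in LT than in A. Of 35 tested, 13 fell and 1 rose with guide 1 (15 and 1 adjusted over the list alone; camera adjusted p = 1.21e-12) and 10 fell with guide 2 (15; adjusted p = 8.83e-09), 7 of them with both. With an estimated correlation these adjusted p were 0.00199 and 0.0147. Of the 13 that had risen with both guides in A, 3 were lower in LT than in A with both. The guide and LT comparisons share the A libraries of each guide with opposite signs, which by itself favours opposite directions. EPAS1 went from 278 ± 15.4 to 98.8 ± 3.25 and from 137 ± 6.45 to 59.2 ± 7.52 CPM. The lipase inhibitor gene ANGPTL4 went from 105 ± 5.66 to 61.5 ± 5.64 and from 17.3 ± 2.20 to 5.91 ± 1.21 CPM, and the lipid droplet gene PLIN2 from 611 ± 47.4 to 295 ± 24.9 and from 211 ± 12.95 to 147 ± 20.5 CPM. Of 30 NF-κB and inflammation genes, 12 fell and 1 rose with guide 1 (17 and 1 adjusted over the list alone; adjusted p = 1.26e-10) and 6 fell and 2 rose with guide 2 (7 and 2; adjusted p = 0.00361). CXCL5 changed by -1.34 ± 0.19 and -2.16 ± 0.21. Of 18 neural genes, 7 fell and 1 rose with guide 1 (7 and 1 adjusted over the list alone; adjusted p = 4.67e-05) and 7 fell and 1 rose with guide 2 (8 and 1; adjusted p = 1.2e-09). The neurofilament gene NEFL went from 112 ± 14.1 to 63.0 ± 5.04 and from 118 ± 7.90 to 25.4 ± 1.18 CPM. The synaptic gene SNAP25 changed by -3.55 ± 0.44 and -1.62 ± 0.31. MAPT, which encodes tau, rose from 1.29 ± 0.21 to 10.9 ± 4.52 and from 1.16 ± 0.22 to 6.57 ± 1.06 CPM. Of 60 cell cycle genes, 8 rose with guide 1 (19 rose and 1 fell adjusted over the list alone; adjusted p = 2.38e-07) and 9 with guide 2 (9; adjusted p = 3.43e-06), 3 of them with both. CCNA2 went from 59.1 ± 3.75 to 87.1 ± 5.12 and from 74.7 ± 1.84 to 101 ± 2.94 CPM, and its guide 2 call was lost without the filter on low counts. Of 18 nephron lineage transcription factors, 5 fell with guide 2, PAX8 among them (5 adjusted over the list alone; adjusted p = 0.00596), and 2 rose and 3 fell with guide 1 (3 and 4; adjusted p = 0.397). As markers of other cells, 2 of 5 fibroblast genes fell with both guides and 1 rose with guide 1 (adjusted p = 0.979 with guide 1 and 0.0149 with guide 2). The guide 2 call gave adjusted p = 0.0633 with an estimated correlation and was lost without the filter on low counts (0.242) and in a fit of the compared groups only (0.0600).

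The 2 SMARCB1 guides also differed from each other in A. TENM2, a teneurin adhesion protein gene, stood at 1.73 ± 0.66 CPM with guide 1 and 28.7 ± 1.91 CPM with guide 2 (log2 fold change of guide 2 against guide 1 of 4.03 ± 0.23). FILIP1L stood at 2.03 ± 0.41 and 23.3 ± 3.79 CPM, the metallothionein gene MT1F at 5.82 ± 0.85 and 52.3 ± 6.39 CPM and CCDC80 at 75.7 ± 3.19 and 484 ± 61.2 CPM. GPR15LG stood at 20.8 ± 3.04 and 2.76 ± 0.91 CPM and PAQR5 at 10.0 ± 2.35 and 1.62 ± 0.68 CPM. ANGPTL4 stood at 105 ± 5.66 and 17.3 ± 2.20 CPM and the chemokine receptor gene CXCR4 at 19.7 ± 1.80 and 3.86 ± 0.61 CPM. SMARCB1 itself did not pass between the guides (log2 fold change 0.32 ± 0.25, edgeR adjusted p = 0.603). Of 35 HIF targets, 18 were lower and 1 higher with guide 2 (22 and 1 adjusted over the list alone; camera adjusted p = 2.05e-33, and adjusted p = 4.24e-05 with an estimated correlation). Of 33 mesenchymal genes, 11 were higher and 1 lower (14 and 3 adjusted over the list alone; adjusted p = 8.85e-07). Of 24 epithelial genes, 5 were lower (5; adjusted p = 0.0051), and of 5 metallothioneins 3 were higher (4; adjusted p = 4.65e-09). In total 850 genes passed between the guides by edgeR, 410 higher and 440 lower with guide 2, and 285 were lower without guide 2 A replicate 1.

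From A to LT the guides diverged in 801 genes by the edgeR test of the interaction, 383 with a more positive and 418 with a more negative change with guide 2, 497 of them by at least 2-fold. CUL9, which encodes a cullin of ubiquitin ligases (ENSG00000112659, chromosome 6, 43182184 to 43224587), went from 5.72 ± 1.43 to 209 ± 64.0 CPM with guide 1 and stood at 6.11 ± 1.45 and 5.55 ± 0.81 CPM with guide 2 (interaction -5.34 ± 0.34). The epithelial surface gene CD24 stood at 7.09 ± 1.42 and 199 ± 82.9 CPM with guide 1 and at 37.8 ± 6.22 and 21.5 ± 0.87 CPM with guide 2 (-5.62 ± 0.35). MAL2, a gene of apical membrane transport in epithelia (ENSG00000147676, chromosome 8, 119165034 to 119245673), rose from 2.57 ± 0.34 to 30.3 ± 1.37 CPM with guide 1 and fell from 7.32 ± 1.25 to 1.47 ± 0.70 CPM with guide 2 (-5.85 ± 0.37). LRATD2 went from 6.61 ± 1.07 to 45.4 ± 17.04 and from 28.3 ± 5.63 to 5.28 ± 1.63 CPM (-5.19 ± 0.37). In the other direction, IGFBP4 stood at 1.52 ± 0.47 and 1.68 ± 0.68 CPM with guide 1 and rose from 0.53 ± 0.40 to 10.99 ± 2.56 CPM with guide 2 (4.17 ± 0.57). The inhibin subunit gene INHBB stood at 5.78 ± 1.37 and 2.75 ± 1.00 CPM with guide 1 and rose from 28.3 ± 1.75 to 157 ± 19.8 CPM with guide 2 (3.56 ± 0.31). The cadherin gene CDH13 fell from 7.95 ± 2.53 to 0.23 ± 0.22 CPM with guide 1 and from 14.97 ± 0.58 to 4.37 ± 1.15 CPM with guide 2 (3.30 ± 0.48, and 3.89 without guide 1 LT replicate 3). APCDD1L-DT fell from 16.6 ± 3.87 to 2.38 ± 0.94 CPM with guide 1 and stood at 21.9 ± 4.17 and 30.5 ± 5.15 CPM with guide 2 (3.27 ± 0.34). The largest edgeR adjusted p of the interaction in these 8 genes was 4.73e-05.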

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

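The tests of shared libraries and of PAX8 recovery for the reversal, and the counts without control replicate 2 and guide 1 LT replicate 4 together, were chosen only after the result was seen.

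The opposite effects of the PAX8 hairpin and the SMARCB1 guides on 440 genes were weighed first. Noise of single shared PAX8 hairpin libraries as the whole cause is argued against by the splits, in which reversed genes outnumbered same-direction genes at least 5.10 times. A deviation common to all PAX8 hairpin libraries would enter both sides of each split, so the splits cannot address it. A return of PAX8 mRNA as the whole cause was examined in the guide 2 LT cells, where PAX8 stood at 86.2% of the PAX8 hairpin mean. At least 95.4% of the reversed genes, chosen with 2 of the PAX8 hairpin libraries and measured against the other 2, were still moved back there. The shift was thus present in LT without raised PAX8 mRNA. With no control guide group under LT, an effect of LT cannot be told apart, and a lasting effect of the PAX8 rise in A is not covered. The question stays open for A. PAX8 protein was not measured. An effect of SMARCB1 loss that opposes that of the hairpin stays open and was not tested. No group had a SMARCB1 guide without the PAX8 hairpin, so whether such an effect needs the hairpin cannot be told. Effects of the PAX8 hairpin on targets other than PAX8 stay open as well and were not tested.

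The SMARCB1 guides differed, which placed both counts here, 850 genes between guides in A and 801 genes in the change from A to LT. In A the log2 differences of guide 2 against guide 1 were 4.03 for TENM2, 3.50 for FILIP1L, 3.17 for MT1F, 2.68 for CCDC80, -2.90 for GPR15LG, -2.62 for PAQR5, -2.60 for ANGPTL4 and -2.35 for CXCR4. In the change from A to LT they were 4.17 for IGFBP4, 3.56 for INHBB, 3.30 for CDH13, 3.27 for APCDD1L-DT, -5.85 for MAL2, -5.62 for CD24, -5.34 for CUL9 and -5.19 for LRATD2. For the remaining PAX8 mRNA as the cause of the divergence, the interaction was set against the hairpin effect across the 2338 genes called for the hairpin. Pearson r was -0.0115 and Spearman rho -0.0691, and genes are not independent replicates. Such a relation is only to be seen where these genes still follow PAX8 in cells with a SMARCB1 guide. That was not shown, so the remaining PAX8 mRNA stays open. Guide 1 LT replicate 4 as the cause of the divergence is argued against by 865 calls without that library. A guide's effect at other sites, the growth of single clones and the residual SMARCB1 level stay open and were not tested.

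Control replicate 2 and guide 1 LT replicate 4 stood apart on the second principal component, at -57.8 and -73.2. For this, 3 technical relations of group-centred values were tested with 100000 permutations within groups. Each was repeated without the 2 libraries farthest out on the technical measure, which need not be the 2 libraries just named. None was repeated with those just named left out by choice. The share of counts in rows without an identifier followed the component over the 20 libraries that have such rows, control replicate 2 not among them (Pearson r -0.512, permutation p = 0.0123, adjusted p = 0.0369; Spearman rho -0.489, permutation p = 0.0268; r -0.668 without the 2 libraries farthest out on that share), so a difference in library make-up may contribute. Sequencing depth was left open (r -0.363, permutation p = 0.15, adjusted p = 0.15; rho -0.494, permutation p = 0.0303; r -0.380 without the 2 libraries farthest out on depth). The relation with the mitochondrial share (r -0.570, permutation p = 0.0417, adjusted p = 0.0626; rho -0.394, permutation p = 0.0635) rested on the 2 libraries farthest out on that share, without which r was -0.181. No biological explanation was tested, as the labels give only a number for each replicate of a group.

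The rows without an identifier are data outside the comparisons, and their share of the counts in a file ran from 53.7% to 66.0% in the 20 files that have them. What these rows counted is not stated.

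Single libraries lay far from the other 3 of their group, with a gap to the nearest, as a share of the group's range, above Dixon's 95% limit, in 23 of 466 group values, where chance alone gives about 23.3. The mitochondrial share of guide 1 A replicate 4 was 13.6% against 11.4% to 11.6% in the others (0.901), and PTGES stood at 17.99 CPM in guide 1 LT replicate 4 against 3.80 to 5.18 CPM (0.903). Further libraries above the limit, with the gap as a share of the range in parentheses, were PAX8 hairpin replicate 1 for TFAP2A (0.834) and FN1 (0.942), PAX8 hairpin replicate 2 for SCG5 (0.884), INHBA (0.838) and AXL (0.962), PAX8 hairpin replicate 3 for DDIT4 (0.953), PAX8 hairpin replicate 4 for ARID2 (0.96), control replicate 1 for FYN (0.882), guide 1 A replicate 1 for SCG5 (0.899), PCLO (0.901), IRX3 (0.913), GINS1 (0.837) and CXCL5 (0.856) and guide 1 A replicate 2 for MT1F (0.872). The same held in guide 1 A replicate 4 for GPR15LG (0.864), guide 1 LT replicate 2 for GINS1 (0.888), guide 1 LT replicate 4 for PLAC8 (0.911), guide 2 A replicate 1 for DDIT4 (0.837), guide 2 A replicate 2 for FYN (0.901), guide 2 A replicate 4 for GASK1B (0.97) and guide 2 LT replicate 2 for CXCL5 (0.868).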

How the results depend on the processing

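The counts without control replicate 2 and guide 1 LT replicate 4 together were chosen after the result was seen. In the order hairpin, guide 1, guide 2, LT minus A with guide 1 and with guide 2, guide 2 against guide 1 in A, their difference in LT minus A, shared by the guides, shared in LT minus A, and reversed, an adjusted p under 0.01 left 1316, 2008, 808, 644, 594, 491, 413, 697, 112 and 235 genes, by its own construction. A fit of the compared groups only gave 2210 for guide 2, 532 for LT minus A with guide 1 and 119 shared in LT minus A, and the cause was not tested. The other settings (DESeq2, limma-voom, DESeq2 size factors, library size alone, no filter, the replicate block) and leaving out 1 replicate kept each of these 10 counts within 1.5 times. Leaving out 1 replicate gave ranges of 1809 to 2159, 2568 to 2792, 1073 to 1195, 872 to 1338, 767 to 1114, 635 to 754, 631 to 865, 927 to 1247, 170 to 281 and 336 to 471 in the same order. Without both libraries above, the counts were 2739, 3661, 1917, 1531, 1558, 1154, 975, 1542, 328 and 568. With replicate number as a block they were 2751, 3375, 1688, 1427, 1298, 1007, 953, 1378, 271 and 522.

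For the target levels in log2(CPM + 1), the SMARCB1 difference of the hairpin ranged from -0.56 to -0.35 over the left-out replicates, with an exact permutation p of 0.05714 without any 1 of the 4 PAX8 hairpin libraries. SMARCB1 in LT minus A with guide 2 ranged from 0.60 to 0.82, passed without guide 2 LT replicate 1 (0.82, exact permutation p = 0.02857) and with library size alone (0.70, exact permutation p = 0.02857), and the cause was not tested. PAX8 in LT minus A with guide 1 ranged from 0.24 to 0.50 and passed without guide 1 LT replicate 3 (0.50, exact permutation p = 0.02857). No called direction reversed in any alternative run. Results without a call could change sign between alternatives. Of 684 results of named genes, called or not, 86 were called and then lost in at least 1 alternative, 74 of them on leaving out 1 replicate. Of 84 list calls, 32 were lost in at least 1 alternative. Scaling moved the median of all genes by at most 0.07 on the log2 scale. Depth limits what a count of 0 can show to 0.261 to 0.383 CPM.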

Other observations

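Further gene lists were tested in the same comparisons, and not each of the 84 list calls is described. Of 25 YAP and TAZ targets, 12 fell and 4 rose with guide 1 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00059) and 7 fell and 3 rose with guide 2 (10 and 3; adjusted p = 0.00645). CCN2 stood at 95.7 ± 10.6 CPM in PAX8 hairpin cells, 20.3 ± 5.39 CPM with guide 1 and 39.9 ± 3.55 CPM with guide 2, while IGFBP3 rose from 106 ± 26.0 to 507 ± 76.2 and 278 ± 42.9 CPM. Of 10 proximal tubule markers, 3 fell with both guides, CDH6 (from 14.9 ± 1.38 to 0.78 ± 0.21 and 4.11 ± 0.79 CPM), CRYAB and AQP1. That list's call with guide 1 (camera adjusted p = 0.0469) gave adjusted p = 0.065 with an estimated correlation, and was lost without PAX8 hairpin replicate 2 (0.0559) or guide 1 A replicate 1, 3 or 4 (0.0536, 0.0791 and 0.0538). It was also lost without the filter on low counts (0.646), with limma-voom (0.354), DESeq2 (0.177), replicate number as a block (0.0640) and library size alone (0.0550), and without control replicate 2 and guide 1 LT replicate 4 together (0.0907), an omission chosen after seeing the data. Its median of 0.30 differs in sign from its mean of -0.59 and the test. The call with guide 2 (adjusted p = 0.0297) was lost without guide 2 A replicate 4 (0.0788), without the filter on low counts (0.146), with limma-voom (0.136) and without control replicate 2 and guide 1 LT replicate 4 together (0.0576). From A to LT 4 of these markers rose and 1 fell with guide 1 (adjusted p = 0.0215), and 2 fell with guide 2 (adjusted p = 0.0431, and adjusted p = 0.0736 with an estimated correlation). The guide 1 call was lost without guide 1 A replicate 1 (0.0561), guide 1 LT replicate 3 or 4 (0.0829 and 0.0583), the filter on low counts (0.452) or both libraries above (0.0555). The guide 2 call was lost without guide 2 A replicate 1 or 2 (0.0662 and 0.0562), guide 2 LT replicate 1, 2 or 3 (0.0561, 0.0667 and 0.0646) or the filter (0.0949), and with limma-voom (0.120). The difference between the guides in that change passed (adjusted p = 0.00735), except without the filter (0.160). Of 5 metallothioneins, 4 rose with guide 2 (4 adjusted over the list alone; adjusted p = 2.8e-10) and 4 fell from A to LT with guide 2 (4; adjusted p = 7.35e-20). With an estimated correlation these adjusted p were 0.000145 and 6.23e-06. MT2A stood at 1972 ± 130 CPM in PAX8 hairpin cells, 5194 ± 312 CPM with guide 2 in A and 1903 ± 370 CPM in LT. Of 25 p53 targets, 7 fell from A to LT with guide 2 (8 adjusted over the list alone; adjusted p = 4.81e-06), among them TP53INP1 (-1.30 ± 0.19), and 1 fell with guide 1, GDF15 (-0.94 ± 0.19). Of 27 SWI/SNF subunits, 2 rose and 2 fell with guide 1 (1 and 1 adjusted over the list alone) and 2 rose and 1 fell with guide 2, SMARCB1 among those that fell and the 2 rises shared by both. The list did not pass (adjusted p = 0.945 with guide 1 and 0.715 with guide 2).

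TGF-β response genes fell with guide 1 (8 of 24 lower, 3 higher; camera adjusted p = 0.00844) and guide 2 (6 and 2; adjusted p = 0.0326). The guide 2 call was lost without guide 2 A replicate 1 (adjusted p = 0.0567) or replicate 4 (0.0544), and without control replicate 2 and guide 1 LT replicate 4 together (0.0576). AP-1 factors fell from A to LT with guide 1 (6 of 21 lower, 1 higher; adjusted p = 0.000409). Cholesterol synthesis genes rose with guide 2 (4 of 24; adjusted p = 0.000551), and their fall with the hairpin (6 of 24; adjusted p = 0.0201) gave adjusted p = 0.0958 with an estimated correlation. HOX genes rose with the hairpin (5 of 30; adjusted p = 0.0285), with adjusted p = 0.0822 with an estimated correlation, and the call was lost without PAX8 hairpin replicate 2 (adjusted p = 0.0556, the highest of the alternatives). Glycolysis genes were lower with guide 2 than with guide 1 (3 of 21; adjusted p = 3.64e-05), as were the ATF4 and unfolded protein response genes (5 of 30 lower, 1 higher; adjusted p = 0.0104, and 0.0693 with limma-voom). Antigen presentation genes (2 of 21 lower; adjusted p = 0.0195) gave adjusted p = 0.0797 with an estimated correlation. Ribosomal protein genes (4 of 46 lower, 0 adjusted over the list alone; adjusted p = 0.0391) and replication histones (3 of 10 higher; adjusted p = 0.0285) in the hairpin comparison gave adjusted p = 0.366 and 0.285 with an estimated correlation. The ribosomal call was lost without control replicate 1 (adjusted p = 0.0937) or PAX8 hairpin replicate 2 (0.0664), and the histone call without control replicate 1 (0.0574) or replicate 4 (0.0818). With library size alone both were lost (0.0562 each), and the ribosomal call also in a fit of the compared groups only (0.0559). NRF2 targets (8 of 22 higher and 2 lower with guide 1; adjusted p = 0.0728), cyclins and CDK inhibitors (2 of 18 higher with the hairpin; adjusted p = 0.862) and nuclear genes of oxidative phosphorylation (3 of 49 higher and 2 lower with the hairpin, 1 and 0 adjusted over the list alone; adjusted p = 0.862) did not pass as lists there. Besides the fibroblast genes, of markers of other cells 1 of 2 endothelial genes rose with the hairpin and 1 fell with guide 1. Of 2 leukocyte genes 1 fell with the hairpin, with each guide and from A to LT with each guide. Of 2 lung epithelial genes 1 rose with guide 1 and 1 was lower with guide 2 than with guide 1.

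Other splits of the libraries were compared with the real grouping, in fits of the compared groups only. For each of these 10 results only 1 split, the real one, gave a count as large. Where replicates may be technical, such splits cannot exclude a chance difference between cultures. For the shared and reversed counts they relabel whole libraries, so they do not test the overlap of real effects. Replicate pairs limit them for guide 2 against guide 1 in A, treated below. For LT minus A with guide 1 and counts built on it, splits that part its pairs were not run. Among 35 splits each, the real grouping and the highest other gave 2136 and 14 genes for the hairpin, 3288 and 0 for guide 1, 2210 and 287 for guide 2, 532 and 0 for LT minus A with guide 1, and 1245 and 14 with guide 2. Among 100 drawn splits each they were 1627 and 0 shared by both guides, 190 and 0 shared in LT minus A, 525 and 408 reversed, and 672 and 438 for the difference between the guides in LT minus A. Guide 2 against guide 1 in A, where libraries with the same replicate number were correlated, gave 940 genes and at most 1 in the 34 other splits. The 8 splits that part all 4 pairs, as the real one does, are too few for a share under 0.05. The others of those 8 gave 0 genes, and with replicate number as a block the real one gave 1619 and the others 0. For the difference between the guides in LT minus A, 100 splits that part these pairs in A were added after seeing the data, and 1 other gave a count as large, 1887 genes. It exchanged the guide labels of all 8 LT libraries and so adds the differences between the guides in A and in LT, a structure of the samples. The next highest gave 479.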
